A study of Sus scrofa with 8 samples.

How the data were processed

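Skeletal muscle RNA of pigs on a high energy diet and pigs on a low energy diet was compared on 8 arrays with 2 colours, each carrying 1 high energy and 1 low energy sample. Per the labels, the arrays form 4 couples of samples, and each couple was hybridised with the dyes one way and then swapped. Couple 1 paired low energy sample 49 with high energy sample 40, couple 2 paired 61 with 41, couple 3 paired 142 with 40 again, and couple 4 paired samples called be and ae, letters that the labels do not expand. The swapped arrays of a couple hold the same 2 RNAs and were averaged to 1 replicate, so n is 4 couples, of which couples 1 and 3 share a high energy sample. The labels do not say whether a sample number stands for 1 animal or a pool, so p-values measure the spread between these couples, which may be partly technical.

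Per the series' design text, RNA was extracted by a modified Chomczynski method, cDNA was labelled with Cy3 and Cy5, low energy samples served as the reference, and the slides were read with a ScanArray LITE scanner. Background correction, spot filter and normalization are not given in the sources used here. The deposited values are log2 ratios of the channels of an array. That unit was read from the values: 5.96% to 19.3% of an array's values were, to the digits given, logarithms of fractions with a denominator up to 60 in base 2, against 0.71% to 2.42% in base e and 2.15% to 4.27% in base 10. Array medians lay between -0.0071 and 0.0115, so the deposited values were already centred near 0; how the authors did this is not given in the sources used here. Most values could also be written as the logarithm of a ratio of 2 small whole numbers, and the larger of them in lowest terms, called the recovered signal here, is a lower bound on the spot's brightness where the value is such a ratio. The lesser number came out under 5000 for 85.9% to 97.1% of values per array, against 0.92% of random values. For the other 2.94% to 14.1% of values the recovered signal may be arbitrary, and they count as bright.

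The direction of the ratios is not stated. The labels put the low energy sample in channel 1 and the high energy sample in channel 2 on every array, and the design text names low energy as the reference, so high over low energy is the likely reading of a positive value and was used as the main one. A rule fixed in advance tested this against ratios of one dye over the other, from the correlation across features of the deviations of a couple's arrays from the mean of their dye orientation. The 4 correlations were 0.013, 0.037, 0.025 and -0.045. They differ in sign, which under that rule leaves the direction unsettled. Each log2 ratio is therefore followed by its turned value, the mean after the sign of the arrays with high energy in dye 3 was reversed. The turned value equals the difference between the dye orientations divided by 2, so it is at the same time the dye effect under the main reading.

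Arrays were centred on their medians. The platform annotation gives 1 gene symbol for 6610 of the 9984 spots, several for 106 and none for 3268. Its accessions are human, none of its 3516 accessions was in the pig RefSeq table, and 2826 of its 2922 symbols also occur in the pig tables. Symbols were kept as given, no coordinates were used, and pig transcripts can bind a human probe unequally. Spots with the same symbol were averaged, and spots without 1 symbol were kept by number, which gave 6296 features. All 3305 pairs of neighbouring named spots shared a symbol, so neighbouring unnamed spots may also be duplicates. Those were counted as separate features. A feature was tested when both orientations were measured in at least 3 couples, which left 5025 features, 2556 of them genes. The test was limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) of the mean ratio against 0, with the high energy sample as a block at a fixed correlation of 0.5, two-sided, with a Benjamini-Hochberg threshold of 0.05. Errors are limma's standard errors over couples.

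Before the data were examined, the tests and 22 gene lists for muscle fibres, metabolism, protein turnover, signalling and other cell types were fixed, with all choices said to be made in advance, and 19 had the 5 measured genes needed for a test. Lists were tested with limma's cameraPR on the moderated t with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 19 lists. An estimated correlation, set to 0 where it came out below 0, and limma's fry were run beside it. The list test was first run on the normal score of each p in place of the moderated t, a departure from the plan. The values given are those of the planned statistic, and the other is kept as an alternative. The genes named in the text were chosen by a rule fixed in advance: the 10 genes with the smallest p in each direction among those with the same sign in all 4 couples, whether or not they passed; from each list, up to 3 members with the smallest p; and the 3 genes with the largest mean ratio among those of the same sign in all 4 couples. Genes outside this rule are said to be so.

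Fixed alternatives were other centring, scaling and quantile normalization, other treatments of the shared sample and of missing values, a fit of all arrays with a dye term, each dye orientation alone, the turned reading, robust variance, spots one by one, each couple left out, and other thresholds. Features with a log2 recovered signal of at least 9, a variance trend on recovered signal, a median over spots, and sets without the most spread arrays or without 1 group of spots were added after the data were seen. For the gene lists, averaging couples 1 and 3, the fit of all arrays with a dye term and features in at least 2 couples were added then as well, having been fixed for features and named genes alone. A correlation between couples estimated from the data, which was also planned, could not be computed, because limma returns none for 4 couples in 3 blocks.

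The fit was tested on simulated couples with the real spread and missing values, 5025 features, of which 67 were changed by 0.5 log2, 67 by 1 and 66 by 2. It called 26.9%, 89.6% and 100% of these, with 11 false calls. Of 50 simulations with no change, 1 had any feature past the threshold and 1 had any list past it. A shift of all 64 ribosomal genes by 0.05 was called in 2 of 20 simulations and a shift by 0.1 in 20. Per array, 7751 to 9427 spots had a value. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.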

Results

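The series addressed how diets of different energy content alter pig skeletal muscle. Muscle cDNA of high energy and low energy animals was hybridised in competition on 8 arrays, in 4 couples of samples with both dye orientations. Values were present for 77.6% to 94.4% of the 9984 spots per array, the SD of the log2 ratios was 0.341 to 0.724, and the median recovered signal was 187 to 607.

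For the comparison of high with low energy muscle, no single gene passed the threshold. Values are the mean log2 ratio ± SE over 4 couples unless another number is given, with the turned value in brackets. For genes measured in 4 couples, the value without a couple is added where leaving it out moved the ratio over 1.5 times or to the other sign. PGAP4, an enzyme that modifies GPI anchors, had a ratio of -0.59 ± 0.086 (turned 0.065) and was below 0 on all 8 arrays. WBP1, which encodes a protein bound by WW domains, had 0.46 ± 0.087 (turned -0.14) and was above 0 on all 8 arrays. PGAM2, the muscle phosphoglycerate mutase of glycolysis, had 0.35 ± 0.089 (turned -0.057), and MYL1, a light chain of fast muscle myosin, had 0.37 ± 0.10 (turned -0.036), both above 0 on all 8 arrays. MYBPC1, the slow type of myosin-binding protein C, had -0.31 ± 0.091 (turned 0.024) and was below 0 on 7 arrays.

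Among the 10 genes with the smallest p above 0, STRAP had 0.42 ± 0.089 (turned 0.19), GMFG 0.35 ± 0.090 (turned 0.28) and SMARCA4, an ATPase of chromatin remodelling, 0.44 ± 0.16 (turned 0.10). LSM7, a component of RNA processing complexes, had 0.50 ± 0.16 (turned -0.16), and NAA38, a subunit of an N-terminal acetyltransferase, had 0.32 ± 0.10 (turned -0.062). SERPINH1, the collagen chaperone, had 0.25 ± 0.086 (turned 0.040), and EEF1A1, a translation elongation factor, had 0.25 ± 0.091 (turned -0.018). Among the 10 below 0, IVNS1ABP had -0.43 ± 0.11 (turned -0.12) and UBA7, the activating enzyme for ISG15, had -0.33 ± 0.086 (turned -0.0062). HAVCR2, an immune receptor, had -0.59 ± 0.18 (turned 0.093), and VWA1, a matrix protein, had -0.40 ± 0.13 (turned -0.069). MAN2C1, a mannosidase, had -0.30 ± 0.085 (turned 0.20), PSMA4, a proteasome subunit, had -0.36 ± 0.10 (turned -0.058), SNN had -0.34 ± 0.095 (turned 0.037) and SCAMP2 had -0.34 ± 0.10 (turned 0.23). Spots of the same gene differed in sign for NAA38, MYBPC1 and VWA1. These 20 ratios correspond to 1.2-fold to 1.5-fold. Of these 20 genes, 7 of those above 0 and 5 of those below 0 kept their sign on all 8 arrays, and 12 had a turned value of the opposite sign. Among named genes with 1 sign in all 4 couples, the largest ratios were those of PPIG at -0.79 ± 0.65 (turned -0.65; -0.28 without couple 3), HNRNPUL1 at -0.75 ± 0.35 (turned 0.70; -0.23 without couple 4) and CAV3, the muscle caveolin, at 0.70 ± 0.37 (turned -0.20; 0.15 without couple 4). PPIG and HNRNPUL1 each rested on 1 array that its dye swap did not repeat: PPIG had -5.29 and -0.023 on the arrays of couple 3, and HNRNPUL1 0.36 and -4.26 on those of couple 4. CAV3 rested on couple 4, whose arrays had 1.42 and 2.54.

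**Figure D1:**
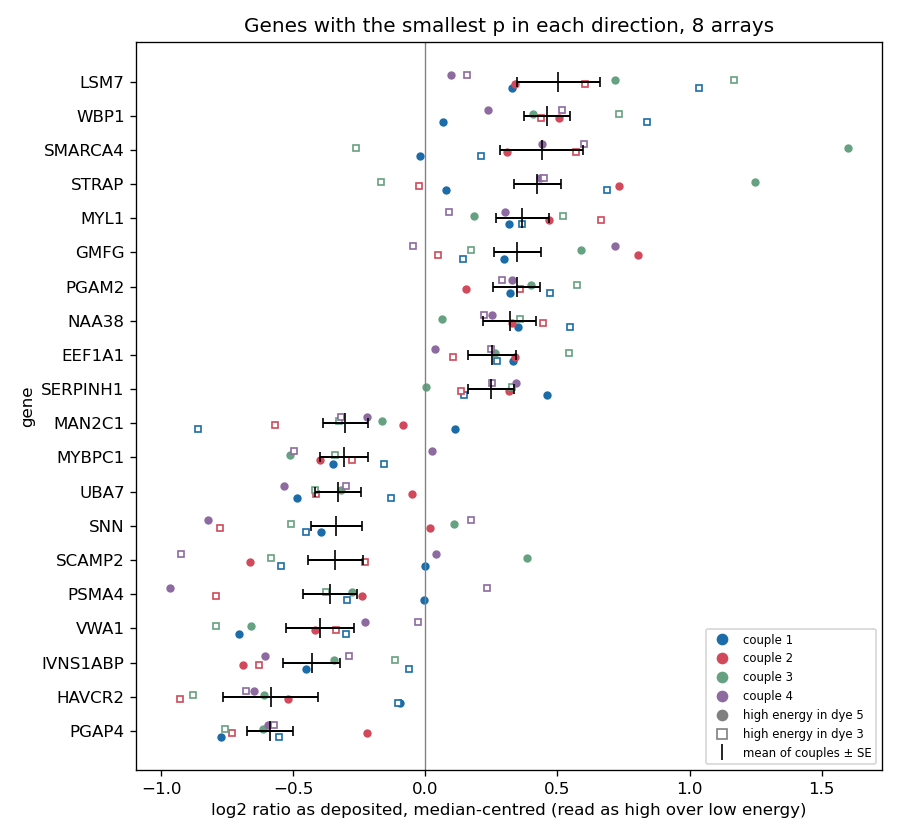
Median-centred log2 ratio (horizontal axis, read as high over low energy) of the 10 genes with the smallest p in each direction among those with the same sign in all 4 couples. Points are the 8 arrays, coloured by couple, filled with high energy in dye 5 and open with it in dye 3, and bars are the mean of 4 couples ± SE. For 7 of the 10 genes above 0 and 5 of the 10 below 0, all 8 arrays lie on one side.

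In limma's test, 0 of 5025 features passed a Benjamini-Hochberg threshold of 0.05, and the smallest adjusted p was 0.996. At an unadjusted p under 0.05 there were 190 features, 69 above 0 and 121 below. Of them 61 were genes and 129 unnamed spots, among which duplicates may count more than once. Turned, there were 133, 71 above 0 and 62 below. High energy in dye 5 alone gave 53 above 0 and 55 below, and in dye 3 alone 71 above 0 and 142 below. Chance gives 251.2 of 5025. Whether the count of 190 lies under it rests in part on the correlation of 0.5 assumed for the shared sample, as independent couples gave 310. Across features, couples 1 and 3 correlated at 0.061, far under 0.5, so the assumed value may make these p-values too large. In 50 simulations with no change that used 0.5, 213 to 287 features had a p under 0.05. A fit of all 8 arrays gave 330. It used a correlation of 0.0039 within couples and so took the arrays of a couple almost as separate replicates. The median size of a ratio was 0.090 and the median SE 0.126. In the simulation with this spread, 89.6% of changes of 1 log2 and 26.9% of changes of 0.5 log2 were called, so a difference of the size seen here would mostly not have been detectable.

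Slow fibre contractile genes lay mostly below 0 and fast fibre genes mostly above it, and neither list passed the main test. Each passed in 1 of 25 alternative settings, with every spot tested on its own. That setting counts the duplicate spots of a gene as separate members. Of 13 slow fibre genes, 11 were below 0, with a mean log2 ratio of -0.075 (turned 0.0055, adjusted p = 0.140). MB, the oxygen store myoglobin, had -0.32 ± 0.10 (turned 0.22). The slow troponins TNNT1 at -0.21 ± 0.080 (turned -0.047) and TNNI1 at -0.21 ± 0.10 (turned 0.078) were below 0 on all 8 arrays, while spots of MB and of TNNT1 differed in sign. Of 12 fast fibre genes, 8 were above 0, with a mean of 0.064 (turned 0.00065, adjusted p = 0.140); TPM1, a tropomyosin, had 0.24 ± 0.11 (turned 0.037), and the fast myosin heavy chain MYH1 had -0.17 ± 0.11 (turned 0.060; -0.27 without couple 2). The 21 sarcomere genes common to fibre types had a mean of -0.034 and a median of 0.00084 (turned mean 0.036, adjusted p = 0.823). Among them, TMOD4 had 0.14 ± 0.084 (turned 0.11) and TCAP -0.32 ± 0.21 (turned 0.083; -0.19 without couple 3 and -0.21 without couple 4).

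Genes of glycolysis and of the citrate cycle had means above 0 and those of oxidative phosphorylation a mean close to 0, and none of these lists passed the main test. The glycolysis list passed in 2 of 25 alternative settings, given below. Of 20 genes of glycolysis and glycogen, 12 were above 0, with a mean of 0.056 (turned 0.039, adjusted p = 0.140). PKM, the pyruvate kinase of muscle, had 0.57 ± 0.21 (turned 0.053) and ENO3, muscle enolase, 0.28 ± 0.14 (turned -0.013), both above 0 on all 8 arrays. Of 13 genes of the citrate cycle and pyruvate entry, 9 were above 0, with a mean of 0.081 (turned -0.042, adjusted p = 0.140). CS, citrate synthase, had 0.27 ± 0.14 (turned -0.019), the kinase PDK2, which inhibits pyruvate dehydrogenase, had 0.37 ± 0.19 (turned 0.029; 0.25 without couple 3), and IDH3G had 0.19 ± 0.098 (turned -0.032). Of 62 nuclear genes of oxidative phosphorylation, 38 were below 0, with a mean of -0.023 (turned -0.0077, adjusted p = 0.862). NDUFB9 had 0.21 ± 0.091 (turned 0.065), NDUFAB1 -0.31 ± 0.14 (turned 0.22) and ATP5F1B, an ATP synthase subunit, -0.17 ± 0.098 (turned -0.013). The 15 genes of fatty acid uptake and oxidation had a mean of 0.010 and a median of -0.017 (turned mean -0.025, adjusted p = 0.862); among them HADHB had 0.22 ± 0.17 (turned -0.14; 0.023 without couple 4), ACADS 0.25 ± 0.20 (turned -0.22; 0.38 without couple 2 and -0.023 without couple 4) and FABP3 -0.092 ± 0.086 (turned -0.020; -0.044 without couple 4). The 8 genes of lipid synthesis and adipocytes had a mean of 0.00076 and a median of -0.057, with the test pointing down (turned mean 0.017, adjusted p = 0.961). RBP4 had -0.075 ± 0.082 (turned 0.17), LIPE 0.31 ± 0.38 (turned -0.12; 0.56 without couple 1 and 0.037 without couple 3) and DGAT2 0.058 ± 0.083 (turned -0.075; 0.097 without couple 4).

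Of 64 cytosolic ribosomal protein genes, 46 were above 0, with a mean of 0.046 ± 0.011 (SE across genes; turned -0.027). The list did not pass at the preset correlation (adjusted p = 0.0659). The estimated correlation was 0 for this list, which treats its genes as independent. With estimated correlations it was the only list past the threshold (adjusted p = 0.00376), and by fry none passed (adjusted p = 0.321 for this list). Without couple 3 the mean was 0.055 (adjusted p = 0.0298 at the preset correlation). On the normal score of each p, the statistic run first, the adjusted p was 0.0352. Couples 1 to 4 had list means of 0.042, 0.076, -0.00090 and 0.048. RPL13 had 0.22 ± 0.082 (turned 0.073), RPL19 0.20 ± 0.095 (turned -0.0028) and RPS29 0.19 ± 0.095 (turned -0.090). The 31 translation factors had a mean of 0.035 (turned 0.026, adjusted p = 0.169; 0.011 without couple 2 and 0.058 without couple 3), with EIF6 at 0.26 ± 0.096 in 3 couples (turned -0.20) and EIF4G2 at 0.38 ± 0.20 (turned 0.11; 0.23 without couple 4).

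Heat shock and folding genes had a mean above 0, and redox genes a mean below 0 in every couple; neither list passed. Of 23 heat shock and folding genes, 18 were above 0, with a mean of 0.077 (turned -0.023, adjusted p = 0.140), and the list mean was 0.25 in couple 4 against 0.058, 0.0074 and -0.065 in couples 1 to 3, and 0.0064 without couple 4. HSPA1A had 0.22 ± 0.089 (turned -0.076), HSPB1 0.26 ± 0.13 (turned -0.10; 0.17 without couple 4) and CCT5 0.25 ± 0.14 (turned -0.28; 0.074 without couple 4). Of 16 redox and metal stress genes, 14 were below 0, with a mean of -0.074 (turned 0.021, adjusted p = 0.240). SOD1, a superoxide dismutase, had -0.24 ± 0.10 (turned -0.025), TXN2 -0.23 ± 0.14 (turned 0.16; -0.15 without couple 3) and TXN 0.13 ± 0.083 (turned -0.14). The 27 genes of ubiquitin, proteasome and proteolysis had a mean of -0.029 (turned -0.017, adjusted p = 0.644; -0.0088 without couple 2 and -0.0049 without couple 4), with the proteasome subunits PSMB5 at -0.30 ± 0.092 in 3 couples (turned -0.041) and PSMC1 at 0.19 ± 0.14 (turned -0.17; 0.094 without couple 3).

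The remaining lists gave no call. The 11 genes of growth factor, insulin and energy signalling had a mean of -0.032 (turned -0.074, adjusted p = 0.862), with IGF2R at -0.29 ± 0.14 in 3 couples (turned 0.050), IGFBP7 at 0.19 ± 0.13 (turned -0.041; 0.34 without couple 2 and 0.10 without couple 4) and IGFBP2 at -0.16 ± 0.11 in 3 couples (turned -0.17). The 8 genes of myogenic regulation had a mean of 0.11 (turned -0.035, adjusted p = 0.401), with a mean of 0.38 in couple 4 and, for the list, 0.18 without couple 1, 0.19 without couple 2 and 0.019 without couple 4. CHRNA1 had 0.21 ± 0.12 (turned -0.096) and MEF2C -0.17 ± 0.10 (turned -0.044), both in 3 couples. The 20 genes of phosphagen and calcium handling had a mean of 0.00067 (turned -0.038, adjusted p = 0.752). FKBP1A had 0.22 ± 0.13 (turned 0.10; 0.36 without couple 2 and 0.11 without couple 4), CACNB1 0.14 ± 0.087 (turned 0.10) and AMPD1 -0.27 ± 0.20 (turned 0.0026; -0.12 without couple 3).

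Markers of other cell types did not pass either. The 11 genes of matrix and fibroblasts had a mean of 0.018 (turned 0.012, adjusted p = 0.473), with COL1A2 at 0.23 ± 0.11 (turned -0.31), COL6A3 at 0.23 ± 0.13 (turned 0.10; 3 couples) and LAMA2 at -0.16 ± 0.093 (turned -0.12; 3 couples). The 7 vessel markers had a mean of 0.13 (turned -0.093, adjusted p = 0.140; 0.045 without couple 4), with EMCN at 0.25 ± 0.12 in 3 couples (turned 0.15), TAGLN at 0.11 ± 0.10 (turned -0.16; 0.065 without couple 1) and MYL9 at 0.19 ± 0.19 (turned -0.32; 0.32 without couple 2 and -0.046 without couple 4). The 11 immune markers had a mean of 0.024 and a median of -0.046 (turned mean -0.027, adjusted p = 0.862), with C1QA at -0.34 ± 0.16 (turned -0.096; -0.17 without couple 2), HLA-DRB1 at 0.19 ± 0.096 (turned 0.011; 0.11 without couple 4) and S100A9 at 0.25 ± 0.13 (turned -0.033). Of the blood markers 4 were measured, too few for a test, among them HBB at 0.038 ± 0.10 (turned 0.094; -0.0042, 0.023, 0.14 without couples 2, 3, 4), HBA1 at -0.025 ± 0.10 (turned 0.029; -0.072, 0.013, 0.0036 without couples 1, 3, 4) and AHSP at -0.27 ± 0.16 (turned 0.17; -0.44 without couple 2 and -0.068 without couple 4). The 1 measured nerve marker, S100B, had 0.37 ± 0.17 in 3 couples (turned -0.15), and 0 of 15 mitochondrially encoded genes had a named spot. No member of any list passed over all features, and 0 passed adjusted over the list alone. With the swapped arrays turned, 0 of the 19 lists passed. No list mean changed sign under the other centring and scaling settings, while leaving out 1 couple turned those of the common sarcomere, oxidative phosphorylation, fatty acid, lipid synthesis, matrix, growth factor, phosphagen and immune lists. Spots of PDK2, HADHB, ACADS, RBP4, NDUFB9, RPL13, HSPB1 and HBB differed in sign within the gene.

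**Figure D2:**
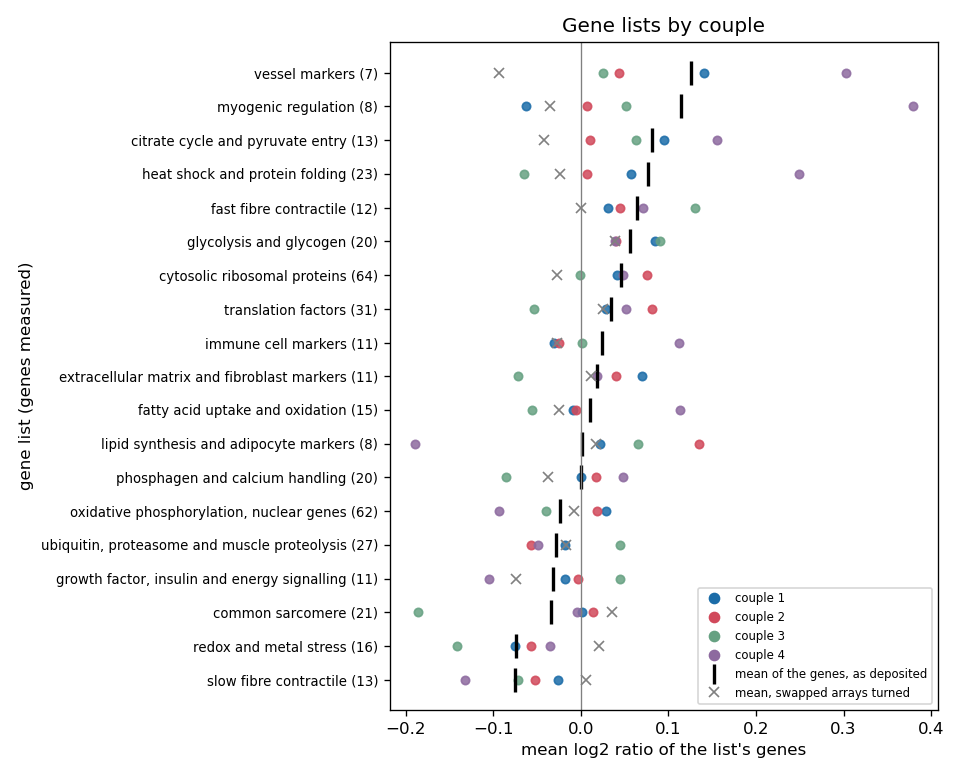
Mean log2 ratio (horizontal axis) of the measured genes of each list, with the number measured in brackets. Points are the 4 couples, black bars the mean of the genes as deposited and crosses the mean with the swapped arrays turned. The ribosomal list mean is 0.046 as deposited and -0.027 turned.

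The turned value, the dye effect under the main reading, had a median size of 0.092 against 0.090 for the diet ratio. Both come from the same 2 arrays of a couple, as their difference divided by 2 and as their mean. Those arrays scarcely correlated (mean rho 0.015), so the 2 sizes would come out alike with no dye or diet effect. At a log2 recovered signal of at least 9, the mean rho between arrays of a couple was 0.071. Between arrays of other couples it was 0.101 with the same dyes (0.019 to 0.222) and 0.044 with swapped dyes (-0.037 to 0.105). A part that follows dye orientation may thus be present, and was not tested. For the turned value 0 features passed in limma (smallest adjusted p = 0.998), and 133 had an unadjusted p under 0.05. Ratios repeated little between couples. Pearson's r across features, which are not independent replicates, was 0.083 between couples 1 and 2, 0.061 between 1 and 3, 0.081 between 1 and 4, -0.012 between 2 and 3, 0.010 between 2 and 4 and 0.022 between 3 and 4. Spearman's rho for the same pairs was 0.053, 0.084, 0.088, 0.0040, 0.023 and 0.039. For features with a log2 recovered signal of at least 9, r was 0.262, 0.246, 0.115, 0.118, 0.052 and 0.062. Their rho was 0.117, 0.211, 0.098, 0.088, 0.084 and 0.079, so the r of couples 1 and 2 rests in part on extreme values. Couples 1 and 3 share a sample, and over the 3640 features on all arrays their r was 0.075, against 0.020 simulated with no diet effect, with covariances of 0.0059 and 0.0016. Of those 3640 features 604, or 16.6%, had 1 sign in all 4 couples (turned 536, or 14.7%). Chance gives 12.5% for independent couples, 12.7% at the simulated r and 16.7% if couples 1 and 3 correlate at 0.5, as assumed in the fit. Their observed r of 0.075 lay far under 0.5, so the last share is likely too high a chance level here.

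A run of 96 neighbouring spots stood apart from the rest of the array, and was looked at only after its values were seen. The platform annotation names 2 of these spots, so the transcripts are not identified here. Their median log2 ratio was -0.23 (turned 0.043), while the medians of the other groups of 96 spots lay between -0.086 and 0.059. The run was not lower on every array: its median was 0.0098 for couple 2 and -0.060 for couple 3 with high energy in dye 5, and between -0.30 and -0.17 on the other 6 arrays. The median recovered signal of the run was 2412, against 381 over all spots. On the first 8 spots of the run, couples 1 to 4 had means of -1.07, -0.79, -0.63 and -0.020.

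**Figure D3:**
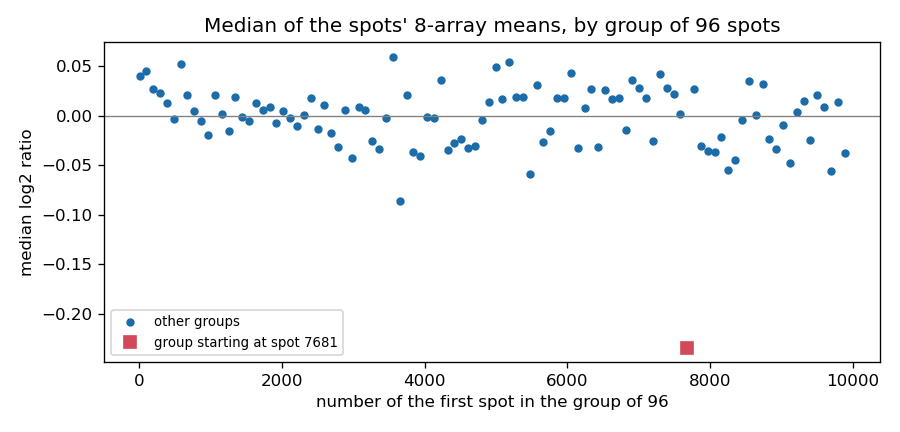
Median log2 ratio (vertical axis, read as high over low energy) of each of the 104 groups of 96 neighbouring spots, against the number of the group's first spot. Each point is the median over a group of the spots' means on 8 arrays; the square, the run of unnamed spots, lies at -0.23 and the other groups between -0.086 and 0.059.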

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

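All tests of the low agreement between arrays in this part were chosen only after that result was seen.

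For 9 named genes, 1 list and 1 measure of the arrays, a value lay far from the others of its set by Dixon's test, in 11 of 93 sets of 4 or 8 values, or 11.8%. Chance marks about 1 set in 20 where values are independent and sets are not selected. Here genes were picked by p, sign or size, and couples 1 and 3 share a sample, so the shares cannot be compared. PPIG, HNRNPUL1 and CAV3 were named for a large mean ratio, which 1 extreme couple can give. Couple 1 had a log2 ratio of -0.099 for HAVCR2, against -0.74 to -0.66 in the other couples. Couple 2 had 0.084 for MYH1, a fast myosin heavy chain, against -0.32 to -0.26. Couple 3 had -2.66 for PPIG (others -0.47 to -0.024), 0.56 for the proteasome gene PSMC1 (others 0.077 to 0.12) and -0.86 for AMPD1, the muscle AMP deaminase (others -0.15 to -0.073). Its mean over the common sarcomere list was -0.19, against -0.0042 to 0.013. Couple 4 had -1.95 for HNRNPUL1 (others -0.33 to -0.075), 1.98 for the caveolin CAV3 (others 0.014 to 0.26), 0.89 for the acyl-CoA dehydrogenase ACADS (others -0.065 to 0.071) and -0.19 for the haemoglobin gene HBB (others 0.12 to 0.15). On the couple 4 array with high energy in dye 5, rho across pairs of duplicate spots was 0.269, against 0.0895 to 0.165 on the other arrays.

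Ratios scarcely repeated from array to array, with a mean rho of 0.023 over 28 pairs of arrays. Dim spots as the whole reason are argued against by a mean rho of 0.0723 among features with a log2 recovered signal of at least 9 (0.0718 without values that gave no small whole numbers). Arrays of a couple hold the same RNAs, and their mean rho for those features was 0.0707. Under the main reading, this argues against differences between the muscle samples as the whole reason. If the ratios follow the dyes instead, differences between the samples would lower this rho and a dye effect would raise it. A low rho could then come from both together, so under that reading the test cannot decide. Spots out of register are argued against for couples 1 to 3, whose recovered signals correlated at rho 0.531 or more (0.286 without those values) while their ratios had a mean rho of 0.027; they stay open for pairs with couple 4, whose lowest was 0.256 (0.116 without those values). Noise between spots may be part of the low agreement, as duplicate spots of the same gene on 1 array correlated at rho 0.0895 to 0.269 (0.162 to 0.364 for bright pairs). What makes them differ, and any biological explanation, was not tested.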

How the results depend on the processing

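The settings with a log2 recovered signal of at least 9, a variance trend on signal, a median over spots, without the most spread arrays, without the run of unnamed spots and with the normal score of each p were chosen only after the data were seen, as were all settings for the same-sign count and for that run of spots. For the gene lists, so were averaging couples 1 and 3, all 8 arrays with a dye term and features in at least 2 couples. The number of features past the threshold stayed at 0 in all 22 settings with a limma test, with smallest adjusted p from 0.136 to 0.999 and 99 to 330 features at an unadjusted p under 0.05 (190 in the planned analysis), and the dye effect gave 0 in each of its settings. Independent couples (310) and all 8 arrays with a dye term (330) lay above the 251.2 of 5025 that chance gives. The fit of all 8 arrays took the arrays of a couple almost as separate replicates, at a correlation of 0.0039. Counts above 5% of their features also came with couples 1 and 3 averaged (256 of 4394), without couple 1 (222 of 4074), without couple 3 (239 of 3960) and at a log2 recovered signal of at least 9 (112 of 1932). Without couple 2 there were 99 of 3716 and without couple 4 100 of 4195. A threshold of 0.10 and a rule of 2-fold with 1 sign in all couples also gave 0, and unadjusted p under 0.05 gave 190. Named genes were tested in 16 to 21 settings each, 33 of the 78 at a log2 recovered signal of at least 9. None passed where it was tested, 28 kept 1 sign in the settings that tested them, and 65 did so apart from the turned reading. A correlation between couples estimated from the data could not be fitted with 3 blocks and was not run. The vessel list had too few genes for a test without couple 2, without couple 3 and for features measured in all 4 couples, and 12 lists could be tested at a log2 recovered signal of at least 9. What signal over background limits was not measured, as background was not used here and recovered signal bounds brightness only from below; 40.8% to 68.5% of an array's values had a log2 recovered signal under 9. Causes were not tested except where stated.

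Lists past the threshold numbered 0 in 17 of 25 settings, and 0 to 1 with a couple left out. The ribosomal list was past it in 8 of 25, with adjusted p over all settings from 0.00361 to 0.853. It passed, as the 1 list, with quantile normalization (mean 0.051, adjusted p = 0.0451), features measured in all 4 couples (0.046, 0.0314), a variance trend (0.046, 0.00733), an estimated correlation of 0 (0.046, 0.00376) and the normal score of each p (0.046, 0.0352). With couples left out its mean was 0.031 to 0.055, past the threshold only without couple 3. At a log2 recovered signal of at least 9, 2 lists passed, the ribosomal (0.054, 0.00361) and the glycolysis list (0.13, 0.0140). With spots tested one by one 4 passed, slow fibre (-0.12, 0.00131), glycolysis (0.077, 0.00131), fast fibre (0.076, 0.0265) and ribosomal (0.033, 0.0265); this setting by construction counts each gene's duplicate spots as separate members. The fast fibre, glycolysis and translation factor lists, 3 in all, kept the sign of their mean in every setting.

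At a log2 recovered signal of at least 9, the mean r between couples was 0.14 against 0.041, and the mean correlation of the direction test 0.046 against 0.0073. With arrays scaled to the same spread the mean r between couples was 0.040, and for features in all 4 couples 0.056. Centring cannot move these correlations. The turned reading gave 25 features with the same sign on all arrays against 82, and a median of 0.043 for the run of spots, which was -0.15 on arrays with high energy in dye 5 alone.

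The turned reading reversed 47 named genes and 11 lists: the slow fibre contractile list 0.0055, the common sarcomere list 0.036, the citrate cycle and pyruvate entry list -0.042, the fatty acid uptake and oxidation list -0.025, the cytosolic ribosomal proteins list -0.027, the heat shock and protein folding list -0.023, the redox and metal stress list 0.021, the myogenic regulation list -0.035, the phosphagen and calcium handling list -0.038, the immune cell markers list -0.027, the vessel markers list -0.093, WBP1 -0.14, PGAM2 -0.057, MYL1 -0.036, LSM7 -0.16, NAA38 -0.062, EEF1A1 -0.018, PGAP4 0.065, MAN2C1 0.20, SNN 0.037, MYBPC1 0.024, SCAMP2 0.23, HAVCR2 0.093, HNRNPUL1 0.70, CAV3 -0.20, MB 0.22, TNNI1 0.078, MYH1 0.060, TCAP 0.083, ENO3 -0.013, NDUFAB1 0.22, CS -0.019, IDH3G -0.032, HADHB -0.14, ACADS -0.22, RBP4 0.17, LIPE -0.12, DGAT2 -0.075, RPL19 -0.0028, RPS29 -0.090, EIF6 -0.20, PSMC1 -0.17, COL1A2 -0.31, HSPA1A -0.076, HSPB1 -0.10, CCT5 -0.28, TXN2 0.16, TXN -0.14, IGF2R 0.050, IGFBP7 -0.041, CHRNA1 -0.096, AMPD1 0.0026, AHSP 0.17, HBA1 0.029, S100A9 -0.033, TAGLN -0.16, MYL9 -0.32 and S100B -0.15. Arrays with high energy in dye 5 alone reversed the common sarcomere list 0.0010, the matrix list -0.017, the phosphagen and calcium handling list -0.034, the immune cell markers list -0.011, RBP4 0.096, DGAT2 -0.017, COL1A2 -0.076, CCT5 -0.029, TXN -0.0073, HBA1 0.0035, TAGLN -0.047 and MYL9 -0.13. Arrays with it in dye 3 alone reversed the lipid synthesis list -0.016, the matrix list -0.014, the growth factor signalling list 0.079, IGFBP2 0.060 and HBB -0.056. Independent couples reversed the phosphagen and calcium handling list -0.0072, and all 8 arrays with a dye term the phosphagen and calcium handling list -0.0057. Averaging couples 1 and 3 reversed the lipid synthesis list -0.0040 and the immune cell markers list -0.0038. Features in all 4 couples reversed the matrix list -0.0024, the growth factor signalling list 0.014 and the immune cell markers list -0.0099, and features in at least 2 couples the matrix list -0.017. A log2 recovered signal of at least 9 reversed the fatty acid uptake and oxidation list -0.0090 and the ubiquitin and proteolysis list 0.0086. A median over spots reversed the lipid synthesis list -0.0050 and HBB -0.021. Leaving out the most spread arrays reversed the lipid synthesis list -0.0090, ACADS -0.097, IGFBP7 -0.0097, HBA1 0.095, EMCN -0.13 and MYL9 -0.097, and spots one by one the fatty acid uptake and oxidation list -0.0057 and the immune cell markers list -0.0033. With 1 couple left out, these means changed sign or side of the threshold: -0.064 to 0.0012 for the common sarcomere list, -0.044 to 0.0034 for the oxidative phosphorylation list, -0.021 to 0.031 for the fatty acid uptake and oxidation list, -0.057 to 0.082 for the lipid synthesis list, 0.031 to 0.055 for the cytosolic ribosomal proteins list, -0.021 to 0.035 for the matrix list, -0.021 to 0.046 for the growth factor signalling list, -0.022 to 0.027 for the phosphagen and calcium handling list, -0.024 to 0.017 for the immune cell markers list, -0.023 to 0.38 for ACADS, -0.0042 to 0.14 for HBB, -0.072 to 0.013 for HBA1 and -0.046 to 0.32 for MYL9.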

Other observations

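The count of features with the same sign on all arrays, its sign patterns, and the tests of one offset and of a dye effect in the run of spots were chosen only after the results were seen.

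On all 8 arrays 82 of 3640 features kept 1 sign, 29 above 0 and 53 below, where 28.4 would be expected by chance. Named genes made up 24 of those above 0 and 17 of those below. The other 36 below 0 were unnamed spots, 19 of them in the run. Some of these were neighbours that may be duplicates of each other, so the count below 0 may be inflated. Besides genes given above, these 4 were chosen after their values were seen. CKM, the muscle creatine kinase read on 22 spots, had a log2 ratio of 0.083 ± 0.080 (turned 0.016), and HAGH, a glyoxalase, had 0.29 ± 0.11 (turned -0.13). VAMP2, a vesicle fusion protein, had -0.35 ± 0.14 (turned 0.25), and HMGN4, a nucleosome-binding protein, had -0.25 ± 0.10 (turned 0.054). None passed the test over all features.

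Of all sign patterns of the 8 arrays, 1, the real one, gave as many as 82 features, and the highest other gave 54 (exact p = 0.0078, the smallest these patterns allow). These patterns treat the 8 arrays as independent, and the count was chosen after the data were seen, so chance is not excluded. Without the run, the real pattern gave 63 features and the highest other 47. The arrays of a couple share RNA, however, and over the 8 sign patterns of the 4 couples, too few for a share under 0.05, the highest other gave 37. The turned reading gave 25 features, which does not settle the direction, since a dye effect of ratios of one dye over the other would also keep 1 sign. For features at an unadjusted p under 0.05, 1 of the 8 patterns of couples, the real one with 190, gave as many, the highest other gave 139, and the patterns are too few for a share under 0.05.

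The ribosomal list had a mean of 0.046 and did not pass the planned test. A trend of the ratio with signal is argued against: the mean lay at percentile 99.9 of 10000 random lists matched on recovered signal, whose central range was -0.054 to 0.021. Such lists treat genes as independent, however. They could also draw from the run of unnamed spots, which was bright and lay below 0. This may have lowered their mean, which was -0.017, and the percentile without the run was not tested. A dye effect, if the ratios are one dye over the other, cannot be told apart from a diet difference, because the mean correlation that would decide it was 0.0073, too close to 0. The list mean was 0.016 with high energy in dye 5 and 0.067 with it in dye 3. A difference between the diets may remain and is a hypothesis only.

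The run of unnamed spots had a median of -0.23. A trend with signal is argued against, since the median lay at percentile 0 of 10000 spot sets matched on recovered signal, whose medians ran from -0.043 to 0.046. One offset for the whole group of spots stays open: the upper quartile, -0.13, also lay at percentile 0 of such sets, which a difference between the samples would give too, but the SD, 0.195, lay at percentile 99.6, wider than a shift alone would leave it. A dye effect would give this median if the ratios are one dye over the other, and the correlations that would decide this should then not lie above 0. Over the spots of the run they were 0.28, 0.33 and 0.50 in couples 1, 2 and 4 and -0.0030 in couple 3, with a mean of 0.277. The rule asked for all 4 couples above 0, so a dye effect stays open. If neighbouring spots of the run are duplicates, all these tests of the run rest on fewer independent values than it has spots. A difference between the diets or between the samples of these couples could also remain, and was not tested.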
